A study of Dorcoceras hygrometricum with 9 samples.

How the data were processed

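Messenger RNA was measured by RNA sequencing in leaves of Boea hygrometrica (also named Dorcoceras hygrometricum), a resurrection plant whose leaves survive the loss of nearly all of their water. The labels give 3 groups. Leaves were dried to a relative water content (RWC, the water in a leaf as a share of the water it holds when fully turgid) of 10%, rehydrated to 50% RWC, or rehydrated to 100% RWC. Each group has 3 libraries, which the series' design text calls biological replicates, and the group and replicate number of each library were taken from its title. The extract protocol names leaf tissue, while the source field of every sample names another plant part. The groups are called here desiccated (10% RWC), 50% rehydrated and 100% rehydrated. Leaves that had never been dried are not analysed here, so no value below is a change from the unstressed state.

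Per the file headers, the authors deposited for each library the count of uniquely assigned reads per gene, with genome coordinates, a length, a description and gene ontology terms. Total RNA was sequenced on the Illumina HiSeq 2000 platform per the labels' protocols. The aligner, the counting tool, its strand setting and the genome build are not given in the sources used here, so coordinates are given by scaffold as the authors wrote them. The lengths of all genes were multiples of 3, and are called coding length here. Each file lists only genes with at least 1 read, and a gene missing from a library was given a count of 0. The RPKM values deposited by the authors equal the count scaled by the gene length and by the library's total count, checked to within a relative difference of 1.97e-08 in every library. The coverage column deposited by the authors gives the percent of the gene length covered by reads. It was used only to compare how completely long genes were covered. The authors also deposited a table of comparisons that holds the mean signal of each group (headed base mean), the ratio of the means as a fold, its log2 value, a p-value and an adjusted p-value. The tool behind that table is not given in the sources used here, and a mean of 0 was written there as 0.001. Its first comparison, 50% rehydrated against desiccated leaves, was set beside the counts. Its second comparison stands beside the same gene identifiers but is out of step with them from line 33 on, in 92.2% of the lines, so it was not used here. Another 6 lines of the table name no gene.

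The library totals lay between 6799129 and 7506857 counts. In all, 24738 genes were listed in at least 1 library and 14620 in all 9. The filter of edgeR (filterByExpr, by group) left 14776 genes, removed 9962, and kept at least 99.81% of the counts of each library. A count of 0 in a group was read as fewer than 3 counts over the group, and a fold against such a group is given as a lower bound from that floor. For genes with 1 to 3 counts in a group, the ratio is given with its 95% interval. Floors and intervals cover counting error only. Coordinates, descriptions and ontology terms are those of the authors. A description that names a protein was found for 13138 genes, 10057 from the Nr database and 3081 from KEGG. No sequences are used here, so reads of near-identical copies, as in the early light-induced family, are uncertain between the copies. Of the 168 genes that the naming rule below took for their change or as list members, 0 overlap another listed gene. Genes named only as the most abundant of a group were not in that check.

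Counts were scaled by trimmed mean of M-values (TMM) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3. All 9 libraries entered a single fit with a term for each group and no other covariate. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. Every adjusted p of a gene below is from this test. Levels are given as CPM, counts as a share of the library total after TMM scaling, as the mean ± SD of 3 libraries, and errors of log2 changes are standard errors of the fit. The comparisons were 50% rehydrated against desiccated, 100% against 50% rehydrated, 100% rehydrated against desiccated, and a test of any difference among the 3 groups. The test was checked on simulated counts in which some genes were changed by a known amount. Of genes with a log2 change of 1 it recovered 90% for 50% rehydrated against desiccated, 93% for 100% against 50% rehydrated and 91% for 100% rehydrated against desiccated. Of genes with a log2 change of 2 it recovered 97.9%, 97.9% and 100% in the same order. False calls made up 6.1%, 7.8% and 9.2% of the simulated calls, above the nominal 5%. Of 14385 to 14401 simulated genes, only 100 were changed by 1 and 96 or 97 by 2, up and down alike. In the data most genes were called, so these rates need not hold there. The simulation also does not test TMM scaling where most genes change.

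Before the data were examined, 33 gene lists were fixed as word patterns searched in the descriptions, and a gene may be in more than 1 list. The lists were LEA proteins and dehydrins, early light-induced proteins, small heat shock proteins, HSP70, HSP90, HSP101 and DnaJ chaperones, heat stress transcription factors, light-harvesting and photosystem proteins, Calvin cycle enzymes, chlorophyll biosynthesis, and chlorophyll breakdown and senescence. Others were cytosolic ribosomal proteins, plastid and mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, proteasome, autophagy, antioxidant enzymes, and raffinose, sucrose and trehalose metabolism. Further lists were cell wall remodelling and synthesis, phenylpropanoid and flavonoid enzymes, aquaporins, ABA synthesis, perception and response, auxin response, cell cycle, DNA replication and kinesins, histones, and splicing factors. The remaining lists were oil body proteins, lipoxygenases and phospholipases, the glyoxylate cycle with beta-oxidation and alternative oxidase, NAC, WRKY and AP2/ERF transcription factors, 3 lists of markers of other tissues (root, flower and pollen, seed storage), and core genes of the organelle genomes as a check of RNA handling. Lists with at least 5 tested members, 30 in all, were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. Camera compares a list with all other genes. The test was repeated with a correlation estimated for each list, and fry (limma), which asks whether the members move one way on balance, was run beside it. On simulated counts, 1 list shifted by a log2 change of 1 was called by both, and 0 of the unshifted lists were. Genes were drawn independently there, so this does not show how camera behaves on lists with correlated members. For aquaporins, 50% rehydrated against desiccated, the estimated correlation was 0.624.

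The genes named were chosen by a rule also fixed before the data were examined. For each comparison, it takes the 5 genes with the largest increase and the 5 with the largest decrease among called genes with a mean CPM of at least 10 over the 9 libraries, a description that names a protein and no overlap between the replicates of both groups. It also takes the 3 members with the lowest p of each called list, for other lists at most 1 called member per direction, and the 3 genes with the highest mean CPM of each group. Not every gene the rule takes is reported here. Principal components were computed on log2 CPM. Alternatives set before the data were examined were DESeq2 size factors or total counts in place of TMM, DESeq2 1.42.0 or limma-voom in place of edgeR, no filter or a stricter filter (CPM of at least 5 in 3 libraries), a fold threshold of 2, an adjusted p under 0.01, fits of only the groups compared, a block on the replicate number, leaving out each library in turn, limma on log2(RPKM + 1), and leaving out the 50 genes with the highest counts. A fit without the 3 libraries numbered 1 and a fit with the trend against coding length removed were chosen after seeing the data, as was the use of every setting for the classes of genes by step and for the overlap with the deposited comparison. Enrichment of gene ontology processes was also chosen after seeing the data and used the 6746 tested genes with a process term as background. Terms with at least 15 genes in that background were tested by the one-sided Fisher's exact test with Benjamini-Hochberg adjustment over 692 tests.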

Results

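Leaves of Boea hygrometrica were sequenced in 3 states: desiccated to 10% RWC, rehydrated to 50% RWC and rehydrated to 100% RWC, with 3 libraries each. Total counts were 7357280, 7109325 and 7338798 in the desiccated libraries, 7223048, 7081520 and 7506857 in the 50% rehydrated ones, and 7480443, 7098324 and 6799129 in the 100% rehydrated ones. At these depths a count of 3 in a library equals 0.4 to 0.441 CPM. The coefficient of variation between replicates beyond counting error was 7.5%. Replicates correlated at r of at least 0.989 in log2 CPM across genes, and libraries of different groups at 0.831 or less. Libraries numbered 1 stood apart from the others of their group. The chi-square per degree of freedom between replicates 2 and 3 was 1.33 in desiccated, 1.84 in 50% rehydrated and 3.1 in 100% rehydrated leaves, against 4.67 and 5.8, 4.33 and 5.97, and 3.98 and 6.37 for the pairs with replicate 1. The first principal component held 73.4% of the variance and the second 22.7%.

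**Figure D1:**
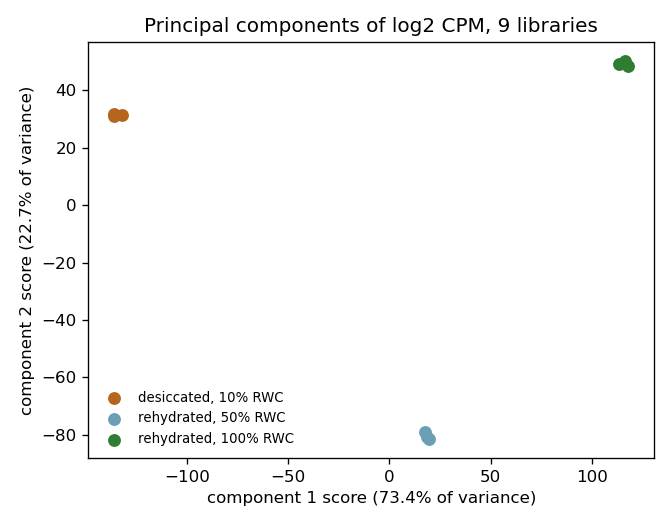
Scores of the 9 libraries on the first principal component (horizontal axis, 73.4% of variance) and the second (vertical axis, 22.7%) of log2 CPM, in arbitrary units, with each point a library and each colour a group. Libraries of a group lie close together, the first component orders the groups by RWC and the second sets the 50% rehydrated leaves apart from both others.

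The most abundant transcripts differed between the states. In desiccated leaves these were a glycine-rich protein 1 (Bhs4783_003V1.1) at 10460 ± 718 CPM (SD, n = 3), a group 3-like late embryogenesis abundant (LEA) protein (Bhs152_037V1.1) at 10230 ± 1110 CPM and an unnamed protein product (Bhs558_007V1.1) at 9452 ± 487 CPM. The LEA transcript stood at 3258 CPM in 50% and 207.6 CPM in 100% rehydrated leaves. In 50% rehydrated leaves, transketolase (Bhs784_020V1.1) led at 8493 ± 741 CPM, followed by the same glycine-rich protein 1 at 7822 ± 590 CPM and a pathogenesis-related protein 10 (Bhs1973_001V1.1) at 6679 ± 69.9 CPM. In 100% rehydrated leaves, the small subunit of RuBisCO (Bhs5191_005V1.1), the carbon-fixing enzyme, led at 17630 ± 3470 CPM, from 248.7 CPM in desiccated leaves. A secretory peroxidase (Bhs14030_001V1.1) at 14660 ± 397 CPM and RuBisCO activase (Bhs7545_001V1.1) at 13250 ± 1070 CPM followed. The 50 most abundant genes took 16.3% to 17.4% of the counts in desiccated, 14.4% to 15.8% in 50% and 21.8% to 24.4% in 100% rehydrated libraries. Some signs of RNA quality and composition moved with the groups. Among genes with a coding length of at least 2000 bases and 50 to 100 reads, the mean covered share was 58.2% to 58.9% in desiccated, 60.9% to 61.8% in 50% and 61.3% to 62.6% in 100% rehydrated libraries. The mean coding length weighted by reads was 1673 to 1710, 1587 to 1630 and 1497 to 1540 bases in the same order. In total, 13687 of 14776 genes (92.6%) differed in any of the 3 groups by edgeR's quasi-likelihood test.

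The step from 10% to 50% RWC asks which transcripts change while dry leaves begin to take up water. Transcripts of phenylpropanoid and flavonoid enzymes, which make lignin precursors and flavonoids, rose in 51 of 64 genes and fell in 11, from a summed 1310 ± 30.7 CPM (SD, n = 3) to 4240 ± 211 CPM. Transcripts of the lipoxygenase and phospholipase list, of cell wall enzymes, of aquaporins, of NAC, WRKY and AP2/ERF transcription factors, of light-harvesting and photosystem proteins, of the Calvin cycle and of chlorophyll biosynthesis also rose as lists at the preset correlation. The phenylpropanoid call held (adjusted p = 0.0204 with an estimated correlation). Those of the other lists were lost (adjusted p = 0.132 to 0.529 with an estimated correlation). Splicing factors fell from a summed 12700 ± 138 CPM to 7310 ± 214 CPM, and translation factors, ribosome biogenesis and autophagy genes fell as lists at the preset correlation, calls that were also lost (adjusted p = 0.132 to 0.419 with an estimated correlation). LEA and early light-induced transcripts did not pass as lists, although the LEA list passed without a filter on low counts (adjusted p 0.0354, with 0.0354 to 0.55 over 17 settings). Summed LEA and dehydrin transcripts still fell, from 36600 ± 4320 to 19500 ± 2180 CPM, with 15 of 26 genes lower and 7 higher. The early light-induced sum stood at 5330 ± 235 CPM before and 5500 ± 413 CPM after this step. Of the 14776 genes, 11693 (79.1%) were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6157 higher and 5536 lower in the 50% rehydrated leaves. Of these, 6171 changed at least 2-fold, 3872 higher and 2299 lower.

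The largest increases among the genes named by the fixed rule came from nearly no expression. An EREBP-like factor, of the ethylene-responsive class of transcription factors (Bhs378_026V1.1, scaffold 378, 133577 to 134215), had no counts in desiccated leaves and 55.3 ± 3.16 CPM (SD, n = 3) in 50% rehydrated ones, at least 379-fold higher. The same held for protein SRG1 (Bhs564_022V1.1, scaffold 564, 448054 to 450112), at 42 ± 0.295 CPM and at least 288-fold higher. A gene described as 1-aminocyclopropane-1-carboxylate, the ethylene precursor (Bhs1022_030V1.1, scaffold 1022, 340055 to 342195), reached 38.5 ± 4.7 CPM and was at least 264-fold higher. An ERF025-like ethylene-responsive factor (Bhs2512_006V1.1, scaffold 2512, 107461 to 108138) reached 29.9 ± 5.75 CPM and was at least 204-fold higher. A phosphate-induced protein (Bhs771_074V1.1, scaffold 771, 569160 to 569990) had 1 count in all desiccated libraries and 1813 in the 50% rehydrated ones, a ratio of 1620 with an interval of 290 to 63800. The largest decreases were of a NAC domain protein (Bhs4896_003V1.1, scaffold 4896, 31480 to 32525), from 79.7 ± 5.94 to 2.28 ± 0.535 CPM, and of integrator complex subunit 11 (Bhs439_003V1.1, scaffold 439, 209838 to 212186), from 32.4 ± 3.66 to 1.39 ± 0.32 CPM. A lysosomal beta glucosidase-like gene (Bhs1259_039V1.1, scaffold 1259, 389332 to 392571) fell from 570 ± 53.2 to 45.3 ± 3.87 CPM. A Gag-Pol polyprotein, a retrotransposon product (Bhs1534_004V1.1, scaffold 1534, 63883 to 64545), and a major latex-like protein (Bhs3665_001V1.1, scaffold 3665, 1998 to 3361) had log2 changes of -3.54 ± 0.14 (SE) and -3.46 ± 0.13. Adjusted p-values of these 10 genes were 3.6e-12 or less, apart from 1.2e-11 for SRG1 and 2.71e-11 for the ERF025-like factor.

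Of the 64 phenylpropanoid and flavonoid genes tested, 51 rose, 11 fell and 2 did not pass, with a median log2 change of 2.50, or 2.37 with genes absent from a group at their bound. Phenylalanine ammonia-lyase (Bhs160_034V1.1), which opens the pathway, rose from 8.13 ± 2.09 to 653 ± 39.3 CPM, and cinnamate 4-hydroxylase (Bhs717_006V1.1), its next enzyme, from 23.3 ± 2.66 to 402 ± 2.92 CPM. A cinnamyl alcohol dehydrogenase-like gene (Bhs32_085V1.1) rose 7.49-fold. The camera test gave an adjusted p of 5.67e-11 for the list, and adjusted p = 0.0204 with an estimated correlation. Counts of members adjusted over the list alone equalled those over all genes in each list and comparison, apart from the exceptions given beside them. Lipoxygenases oxidise fatty acids for jasmonate and other oxylipins. The list of lipoxygenases and phospholipases had 30 of 51 genes higher and 13 lower (adjusted p of camera 0.00196, adjusted p = 0.136 with an estimated correlation). A lipoxygenase (Bhs2748_005V1.1) rose from 12.7 ± 1.83 to 638 ± 31.7 CPM, allene oxide synthase (Bhs7_134V1.1), an enzyme of jasmonate synthesis, from 1.75 ± 0.651 to 478 ± 46.5 CPM, and a phospholipase D (Bhs3093_005V1.1) 23.1-fold. Among NAC, WRKY and AP2/ERF transcription factors, 84 of 133 rose (85 adjusted over the list alone) and 36 fell (adjusted p of camera 0.000326, adjusted p = 0.204 with an estimated correlation). The WRKY genes Bhs45_140V1.1, Bhs3559_008V1.1 and Bhs4126_008V1.1 rose by log2 changes of 7.47 ± 0.13, 7.82 ± 0.15 and 5.48 ± 0.11.

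Of 110 genes of cell wall remodelling and synthesis, 66 rose and 19 fell, with a median log2 change of 1.88, or 1.78 with absent genes at their bound (adjusted p of camera 9.04e-05, adjusted p = 0.18 with an estimated correlation). A cellulose synthase (Bhs71_020V1.1) rose from 11.4 ± 1.08 to 177 ± 5.43 CPM and xyloglucan endotransglucosylase/hydrolase 7 (Bhs280_024V1.1), which cuts and rejoins wall xyloglucan, from 3.34 ± 1.47 to 292 ± 12.1 CPM. A polygalacturonase inhibitor-like gene in this list (Bhs225_013V1.1), a class that acts against pectin-degrading enzymes rather than on the wall, rose 83.3-fold. Of 11 aquaporins, the water channels of membranes, 9 rose and 2 fell, with a median of 1.80, or 3.88 without the 50 genes with the highest counts (adjusted p of camera 0.0325, adjusted p = 0.529 with an estimated correlation). Aquaporin PIP2.2 (Bhs95_066V1.1) rose from 0.287 ± 0.374 to 96.4 ± 22.1 CPM, and another PIP aquaporin (Bhs3276_001V1.1) rose 2.57-fold. A further aquaporin-like gene (Bhs7229_002V1.1) had 2 counts in the desiccated and 367 in the 50% rehydrated libraries, a ratio of 163 with an interval of 44.9 to 1350. In the light-harvesting and photosystem list, 25 of 34 genes rose and 3 fell, with a median of 1.09 (adjusted p of camera 9.01e-05, adjusted p = 0.381 with an estimated correlation). The photosystem II 22 kDa component (Bhs51_010V1.1) rose from 4.04 ± 0.479 to 70 ± 7.35 CPM and a chlorophyll a/b binding protein (Bhs29_032V1.1) from 133 ± 7.14 to 695 ± 17.7 CPM. Calvin cycle enzymes had 14 of 21 genes higher and 3 lower, with a median of 0.75 (adjusted p of camera 0.00123, adjusted p = 0.132 with an estimated correlation). Members of low p included glyceraldehyde-3-phosphate dehydrogenase B (Bhs3223_009V1.1), 9.02-fold higher, and phosphoribulokinase (Bhs6932_002V1.1), 7.98-fold higher. Chlorophyll biosynthesis had 11 of 14 genes higher and 0 lower, with magnesium chelatase (Bhs68_009V1.1) up 9.18-fold and protochlorophyllide oxidoreductase (Bhs200_106V1.1) 4.4-fold (adjusted p of camera 0.00687, adjusted p = 0.132 with an estimated correlation).

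Among splicing factors, 61 of 92 fell and 14 rose, with a median log2 change of -0.49 (adjusted p of camera 0.000176, adjusted p = 0.132 with an estimated correlation). The U4/U6 component PRP3 (Bhs3740_004V1.1) fell from 28.3 ± 0.901 to 2.73 ± 0.304 CPM and SLU7-A-like (Bhs3883_013V1.1) from 571 ± 55.3 to 149 ± 13.8 CPM. Of 83 translation factors, 52 fell and 16 rose, with a median of -0.40 (adjusted p of camera 0.00123, adjusted p = 0.18 with an estimated correlation). Initiation factor iso4G (Bhs85_076V1.1) fell from 584 ± 17.8 to 205 ± 7.32 CPM and a factor 5B gene (Bhs1846_019V1.1) from 933 ± 69.9 to 205 ± 8.99 CPM. Of 83 ribosome biogenesis genes, 50 fell and 13 rose, with a median of -0.41 (adjusted p of camera 0.00687, adjusted p = 0.419 with an estimated correlation). Nucleolar protein 4 (Bhs3030_015V1.1) and a nucleolin (Bhs911_014V1.1) had log2 changes of -1.28 ± 0.07 and -1.49 ± 0.08, while another nucleolin (Bhs5_159V1.1) rose 6.76-fold. Over these groups, the covered share of long genes was 2.72 percentage points higher in 50% rehydrated than in desiccated leaves. Of 12 autophagy genes, 8 fell and 1 rose, with autophagy-related protein 9 (Bhs12_112V1.1) down from 295 ± 8.38 to 89.2 ± 3.18 CPM and autophagy protein 5 (Bhs4989_007V1.1) from 116 ± 3.79 to 33 ± 2.66 CPM (adjusted p of camera 0.0322, adjusted p = 0.18 with an estimated correlation).

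The other lists did not pass camera in this step. Of 26 LEA and dehydrin genes, 7 rose and 15 fell, with a median of -0.65 (adjusted p 0.274). A gene described as an LEA hydroxyproline-rich glycoprotein (Bhs1259_035V1.1) rose from 3.76 ± 0.71 to 243 ± 27.4 CPM. It is in the list by the words of its description, which do not show that it protects dry cells. LEA protein D-34 (Bhs1227_002V1.1) fell 3.98-fold. Of 13 early light-induced genes, whose products bind pigments under light stress, 7 rose and 3 fell (median 0.47, adjusted p 0.245), and Bhs9122_001V1.1 stood at 328 ± 18.9 CPM before and 1290 CPM after the step. Small heat shock proteins had 3 of 10 genes higher and 4 lower, with a median of -0.21, a mean of 0.54 and a test pointing down (adjusted p 0.768). The HSP70, HSP90, HSP101 and DnaJ chaperones had 29 of 106 higher and 56 lower, with a median of -0.37 and a test pointing down but a mean of 0.04 (adjusted p 0.245), while Heat shock protein 90 (Bhs7_048V1.1) rose from 21.7 ± 3.46 to 781 ± 70.8 CPM. Heat stress transcription factors had 3 of 18 higher and 9 lower (adjusted p 0.123), with factor A3 (Bhs49_049V1.1) 3.37-fold lower. Proteasome genes had 19 of 57 higher and 22 lower (adjusted p 0.819), with a median of 0.00, a mean of 0.25 and a camera test pointing down, and the median was 0.16 under total count scaling. Cytosolic ribosomal proteins had 52 of 88 higher (51 adjusted over the list alone) and 11 lower (adjusted p 0.212), and plastid and mitochondrial ones 18 of 31 higher and 5 lower (adjusted p 0.271). Antioxidant enzymes had 40 of 65 higher and 16 lower (adjusted p 0.212), with manganese superoxide dismutase (Bhs109_028V1.1) up from 55.6 ± 4.34 to 397 ± 6.34 CPM and a monodehydroascorbate reductase (Bhs30_086V1.1), which regenerates ascorbate, down 2.67-fold.

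Raffinose, sucrose and trehalose metabolism had 15 of 29 genes higher and 9 lower (adjusted p of camera 0.206), with a raffinose synthase (Bhs30_090V1.1) up 11.3-fold and a trehalose-6-phosphate synthase (Bhs6_077V1.1) down 4.05-fold. In the ABA list, 31 of 62 genes rose and 25 fell (adjusted p 0.461), and in the auxin list 47 of 84 rose and 21 fell (adjusted p 0.125), with an auxin median of 0.74, or 0.70 with absent genes at their bound. Cell cycle, DNA replication and kinesin genes had 57 of 108 higher and 30 lower (adjusted p 0.547), and histones 24 of 37 higher and 5 lower (adjusted p 0.325). Summed CPM went against the counts of genes for cell cycle (6080 ± 215 to 4450 ± 150), raffinose (11900 ± 344 to 9750 ± 214), antioxidant (10300 ± 256 to 9880 ± 187) and ABA genes (3760 ± 22.2 to 3560 ± 49 CPM). The lowest-p decrease in the histone list was of a histone methyltransferase (Bhs32_067V1.1), which modifies histones and is not one. Chlorophyll breakdown and senescence had 4 of 9 genes higher and 2 lower (adjusted p 0.522), and the glyoxylate cycle, beta-oxidation and alternative oxidase list 2 of 9 higher and 5 lower (adjusted p 0.387). Of the core organelle genes, 10 of 18 rose and 2 fell (adjusted p 0.328). The word pattern of that list also took genes whose products are encoded in the nucleus of plants, such as psbY (Bhs8788_004V1.1) and a psbB maturation factor (Bhs8006_001V1.1). Among markers of other tissues, 4 of 4 flower and pollen genes were higher, 2 of 8 seed storage genes were higher and 5 lower (adjusted p 0.365), and 0 of 3 root genes passed the filter. The 3 oil body genes had 0 higher and 1 lower, a caleosin (Bhs39_021V1.1) with a log2 change of -0.65 ± 0.06. Without a filter on low counts, heat stress transcription factors (adjusted p 0.0354, with 0.0354 to 0.168 over 17 settings), cytosolic ribosomal proteins (0.000622, with 0.000622 to 0.276), plastid and mitochondrial ones (0.0119, with 0.0119 to 0.331), auxin genes (0.0269, with 0.0269 to 0.18) and histones (0.0284, with 0.0284 to 0.413) passed as well. The autophagy list no longer passed without the 3 libraries numbered 1 (adjusted p 0.0532, with 0.00831 to 0.0532 over 17 settings), a setting chosen after seeing the data. Total count scaling in place of TMM raised all log2 changes of this step by 0.166, which moved the higher share of calls from 52.7% to 59.5%, and the changes given here are relative to TMM scaling.

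The step from 50% to 100% RWC asks which transcripts change as the leaves regain full water content. All 13 early light-induced transcripts fell, from a summed 5500 ± 413 CPM (SD, n = 3) to 17.7 ± 3.49 CPM, and LEA and dehydrin transcripts fell from 19500 ± 2180 to 4260 ± 488 CPM. Light-harvesting and photosystem transcripts rose from 13800 ± 1720 to 58900 ± 6030 CPM. As lists, the calls held for early light-induced and LEA genes (adjusted p = 0.0486 with an estimated correlation) and were lost for the light-harvesting genes (adjusted p = 0.133 with an estimated correlation). The Benjamini-Hochberg method gave the same camera value of 0.0486 to all 9 lists whose calls held in this step, a tie just under 0.05. Calvin cycle transcripts rose from 11000 ± 955 to 47000 ± 5190 CPM (adjusted p = 0.0486 with an estimated correlation), with a list median of 0.36 on the log2 scale. The small subunit of RuBisCO (Bhs5191_005V1.1), from 2478 to 17630 CPM, and RuBisCO activase (Bhs7545_001V1.1), from 2429 to 13250 CPM, held most of the sum in 100% rehydrated leaves. Phenylpropanoid and flavonoid transcripts fell from 4240 ± 211 to 1580 ± 73.3 CPM (adjusted p = 0.0486 with an estimated correlation). In this comparison, 10547 genes (71.4%) were called by edgeR's quasi-likelihood test, 5518 higher and 5029 lower in 100% rehydrated leaves, and 4840 changed at least 2-fold, 2539 higher and 2301 lower. Which direction held more calls depended on the setting, with 4978 higher and 5522 lower under total count scaling, 5204 and 5612 with limma on log2(RPKM + 1), and 5594 and 5611 without a filter on low counts.

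**Figure D2:**
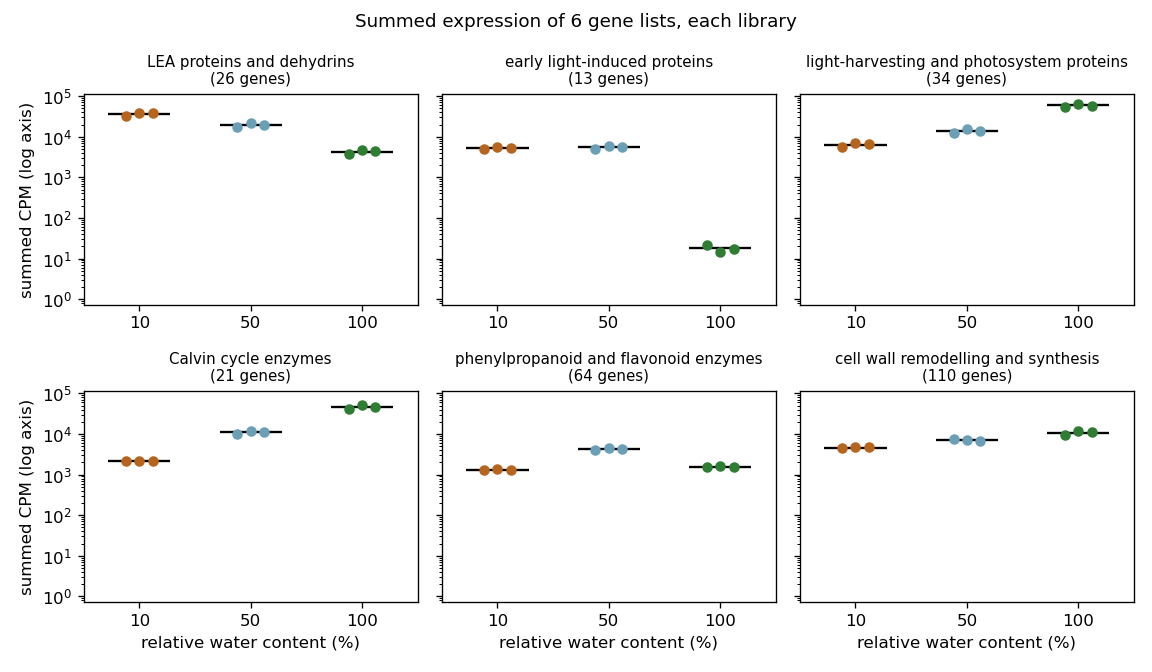
Summed CPM of the tested members of 6 gene lists (vertical axis, log scale, CPM) in each library at 10, 50 and 100% RWC (horizontal axis), with points for libraries and bars for the mean of 3. Early light-induced transcripts were at 5330 CPM in desiccated, 5500 CPM in 50% rehydrated and 17.7 CPM in 100% rehydrated leaves, and phenylpropanoid transcripts at 1310, 4240 and 1580 CPM.

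The largest increases among the genes named by the rule were of wall-related and chloroplast genes. Both expansins named by the rule, proteins that loosen the wall, rose, Bhs109_026V1.1 (scaffold 109, 115320 to 116242) from 0.39 ± 0.0143 to 424 ± 58.3 CPM and Bhs1161_003V1.1 (scaffold 1161, 61759 to 62994) from 2.08 ± 0.224 to 365 ± 51.7 CPM. An endoglucanase (Bhs292_007V1.1, scaffold 292, 89514 to 93045) rose 69.9-fold, a proline-rich protein (Bhs168_020V1.1, scaffold 168, 114693 to 116018) 51.6-fold and a thylakoid membrane phosphoprotein (Bhs387_013V1.1, scaffold 387, 106699 to 108371) 50.5-fold. Protein SRG1 (Bhs564_022V1.1) fell from 42 ± 0.295 CPM to no counts, at least 299-fold lower, and a TGA transcription factor (Bhs6708_008V1.1, scaffold 6708, 40447 to 41373) from 18.9 ± 2.95 CPM to no counts, at least 134-fold lower. The other decreases were of early light-induced genes, Bhs9122_001V1.1 (scaffold 9122, 6461 to 7265) with a log2 change of -10.40 ± 0.16 (SE), Bhs2978_003V1.1 (scaffold 2978, 35747 to 36494) with -9.40 ± 0.18 and Bhs6596_001V1.1 (scaffold 6596, 2252 to 2993) with -9.27 ± 0.23. Adjusted p-values of these genes were 1.24e-11 or less, except 7.41e-10 for the TGA factor.

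All 13 early light-induced genes fell, with a median log2 change of -8.23, or -8.11 with absent genes at their bound (adjusted p of camera 7.76e-32, adjusted p = 0.0486 with an estimated correlation). Reads of near-identical copies are uncertain between single genes of this family, while the summed CPM does not depend on which copy they were given to. The counts are of uniquely assigned reads, so reads that fit several copies may be missing from the sum. Of the LEA and dehydrin genes, 25 of 26 fell and 0 rose, with a median of -2.59 (adjusted p of camera 1.53e-16, adjusted p = 0.0486 with an estimated correlation). An LEA gene (Bhs31748_001V1.1) fell from 650 ± 23.7 to 3.1 ± 1.01 CPM, another (Bhs267_026V1.1) from 1970 ± 58.6 to 310 ± 5.04 CPM, and desiccation-related protein PCC3-06-like (Bhs6899_001V1.1) from 413 ± 20.2 to 46.4 ± 3.82 CPM. In the light-harvesting and photosystem list, 28 of 34 genes rose and 5 fell, with a median of 2.05 (adjusted p of camera 1.25e-08, adjusted p = 0.133 with an estimated correlation). Its word pattern also took 4 of the early light-induced genes, among them Bhs9122_001V1.1. A chlorophyll a/b binding protein (Bhs29_032V1.1) reached 5760 ± 178 CPM from 695 ± 17.7 CPM. Calvin cycle enzymes had 13 of 21 genes higher and 2 lower (adjusted p of camera 0.000353, adjusted p = 0.0486 with an estimated correlation), with phosphoribulokinase (Bhs6932_002V1.1) up from 444 ± 21.7 to 2720 ± 148 CPM. Chlorophyll biosynthesis had 10 of 14 higher and 1 lower (2 lower adjusted over the list alone), with protochlorophyllide oxidoreductase (Bhs200_106V1.1) up 4.81-fold (adjusted p of camera 0.00055, adjusted p = 0.0486 with an estimated correlation). Plastid and mitochondrial ribosomal proteins had 20 of 31 higher and 1 lower (adjusted p of camera 0.00951, adjusted p = 0.118 with an estimated correlation). Of the core organelle genes, 14 of 18 rose and 1 fell (adjusted p of camera 0.00398, adjusted p = 0.0486 with an estimated correlation). Members of low p included 2 psbP genes (Bhs1317_004V1.1 and Bhs442_012V1.1), which are encoded in the nucleus of plants, and atpA (Bhs419_018V1.1), up 2.64-fold.

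Among phenylpropanoid and flavonoid genes, 38 of 64 fell (39 adjusted over the list alone) and 18 rose, with a median of -1.16 (adjusted p of camera 1.68e-05, adjusted p = 0.0486 with an estimated correlation). Phenylalanine ammonia-lyase (Bhs160_034V1.1) fell from 653 ± 39.3 to 59.7 ± 2.8 CPM and cinnamate 4-hydroxylase (Bhs717_006V1.1) from 402 ± 2.92 to 62.1 ± 1.48 CPM. NAC, WRKY and AP2/ERF transcription factors had 73 of 133 genes lower and 39 higher (40 adjusted over the list alone), with WRKY II (Bhs1501_011V1.1) down from 107 ± 5.79 to 1.51 ± 0.356 CPM (adjusted p of camera 0.00398, adjusted p = 0.218 with an estimated correlation). The list also holds SNAP33 (Bhs5_002V1.1), a membrane fusion protein and no transcription factor, which fell 6.62-fold. Lipoxygenases and phospholipases had 31 of 51 lower (32 adjusted over the list alone) and 12 higher, with allene oxide synthase Bhs198_043V1.1 down from 536 ± 16.2 to 105 ± 3.64 CPM (adjusted p of camera 0.00433, adjusted p = 0.0639 with an estimated correlation). In the ABA list, 35 of 62 genes fell and 14 rose (adjusted p of camera 0.00407, adjusted p = 0.0486 with an estimated correlation). ABA 8'-hydroxylase (Bhs4_108V1.1), which breaks ABA down, fell 7.76-fold, and protein phosphatases 2C (Bhs862_005V1.1 and Bhs2663_018V1.1) fell 8.17-fold and 14.5-fold. Raffinose, sucrose and trehalose metabolism had 17 of 29 lower and 10 higher (adjusted p of camera 0.00139, adjusted p = 0.0486 with an estimated correlation), with sucrose synthase 2 (Bhs983_003V1.1) down from 1550 ± 18.5 to 46.5 ± 2.88 CPM. The summed CPM of that list stood at 14100 ± 795 in 100% and 9750 ± 214 CPM in 50% rehydrated leaves.

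Proteasome genes had 44 of 57 members lower and 5 higher, with subunit RPN7 (Bhs734_017V1.1) down 2.49-fold (adjusted p of camera 0.00256, adjusted p = 0.0486 with an estimated correlation). The glyoxylate cycle, beta-oxidation and alternative oxidase list had 7 of 9 lower and 2 higher (adjusted p of camera 0.0102, adjusted p = 0.0736 with an estimated correlation), with mitochondrial alternative oxidase (Bhs211_008V1.1) down from 37.1 ± 2.65 to 2.83 ± 0.43 CPM. Of cell wall genes, 62 of 110 rose (63 adjusted over the list alone) and 27 fell (adjusted p of camera 0.00211, adjusted p = 0.18 with an estimated correlation). In the auxin list, 51 of 84 rose and 17 fell (adjusted p of camera 0.0276, adjusted p = 0.18 with an estimated correlation). Of its members, a SAUR gene (Bhs750_002V1.1) and GH3.6 (Bhs9662_001V1.1), an enzyme that conjugates auxin, fell 40.8-fold and 3.64-fold. Aquaporins had 6 of 11 genes higher and 1 lower and did not pass (adjusted p of camera 0.0597). They passed without 50% rehydrated replicate 2 (0.0301), without 100% rehydrated replicate 1 (0.0337), under total count scaling (0.0387), with no filter (0.0323) or a stricter one (0.0345), without the 50 genes with the highest counts (0.0499) and, a setting chosen after seeing the data, without the 3 libraries numbered 1 (0.0373), with 0.0231 to 0.0774 over 17 settings. The auxin call ended under the stricter filter on low counts (adjusted p 0.107) and, a setting chosen after seeing the data, without the 3 libraries numbered 1 (0.0559), with 0.000272 to 0.107 over 17 settings.

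Other lists did not pass in this step, although without a filter on low counts cytosolic ribosomal proteins (adjusted p 0.00066, with 0.00066 to 0.291 over 17 settings) and translation factors (0.00323, with 0.00323 to 0.264) did. Cytosolic ribosomal proteins had 44 of 88 genes lower (42 adjusted over the list alone) and 6 higher (adjusted p of camera 0.211), translation factors 45 of 83 lower (46 adjusted over the list alone) and 22 higher (0.203), ribosome biogenesis 32 of 83 lower and 21 higher (0.906), and splicing factors 32 of 92 lower (30 adjusted over the list alone) and 19 higher (0.906). The factor 5B gene Bhs1846_019V1.1 fell further, from 205 ± 8.99 to 2.43 ± 1.31 CPM, while another factor 5B gene (Bhs2_082V1.1) rose 3.49-fold. The HSP70, HSP90, HSP101 and DnaJ chaperones had 28 of 106 higher and 40 lower (adjusted p 0.35), with a median of 0.02 against a mean of -0.13 and a test pointing down, and a median of -0.07 under total count scaling. Small heat shock proteins had 2 of 10 higher and 5 lower (0.837), and heat stress transcription factors 6 of 18 higher and 8 lower (0.333), with factor A3 (Bhs49_049V1.1) down from 41.3 ± 1.72 to 7.35 ± 1.17 CPM. Antioxidant enzymes had 28 of 65 higher and 24 lower, with a median of 0.18 and a mean of 0.06 but a test pointing down (0.906). A glutathione peroxidase (Bhs4_048V1.1) fell 4.78-fold and an ascorbate peroxidase (Bhs649_051V1.1) rose 6.65-fold. Autophagy had 5 of 12 higher and 3 lower (0.522), and chlorophyll breakdown and senescence 4 of 9 higher and 4 lower (0.22), with stay-green protein 1 (Bhs427_016V1.1) down from 226 ± 25 to 21.3 ± 1.6 CPM. Cell cycle genes had 41 of 108 higher and 26 lower (0.56), and histones 18 of 37 higher and 7 lower (0.374). Summed CPM again went against the counts of genes for cell cycle (4450 ± 150 to 3520 ± 111) and antioxidant genes (9880 ± 187 to 9210 ± 267), and also for small heat shock proteins (225 ± 2.8 to 252 ± 5.95 CPM). The lowest-p decrease in the cell cycle list was of a CDC48 homolog (Bhs160_038V1.1), an ATPase that also serves protein degradation. Seed storage markers had 2 of 8 higher and 4 lower (0.413), flower and pollen markers 2 of 4 higher and 2 lower, and oil body genes 1 of 3 higher and 1 lower, with the caleosin Bhs39_021V1.1 down from 357 ± 9.27 to 50.3 ± 1.67 CPM. Total count scaling turned the medians of heat stress transcription factors from 0.00 to -0.08 and of oil body genes, whose mean was -0.35, from 0.04 to -0.04.

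The comparison of 100% rehydrated with desiccated leaves spans both steps. Light-harvesting and photosystem transcripts stood at 58900 ± 6030 CPM (SD, n = 3) summed, against 6290 ± 663 CPM in desiccated leaves, and Calvin cycle transcripts at 47000 ± 5190 against 2170 ± 43 CPM. The Calvin cycle median was 1.19 on the log2 scale, and most of the sum in 100% rehydrated leaves, though not in desiccated ones, was in the RuBisCO small subunit and activase named above. LEA and dehydrin transcripts stood at 4260 ± 488 against 36600 ± 4320 CPM, and early light-induced transcripts at 17.7 ± 3.49 against 5330 ± 235 CPM. Cell wall transcripts were higher, at 10700 ± 1000 against 4640 ± 206 CPM. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.0659 with an estimated correlation for the Calvin cycle, and 0.116 for each of the others). By edgeR's quasi-likelihood test, 12427 genes (84.1%) differed, 6554 higher and 5873 lower in 100% rehydrated leaves, and 8035 by at least 2-fold, 4629 higher and 3406 lower.

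The largest increases among the genes named by the rule included the phosphate-induced protein Bhs771_074V1.1, at 205 ± 24.7 CPM with a count ratio of 4210 (interval 755 to 166000), and the expansin Bhs109_026V1.1, at 424 ± 58.3 against 0.239 ± 0.294 CPM. The EREBP-like factor Bhs378_026V1.1, with no counts in desiccated leaves, was at least 111-fold higher. An aldehyde dehydrogenase of family 3 (Bhs11746_001V1.1, scaffold 11746, 7844 to 17092) reached 186 ± 7.5 from 0.195 ± 0.169 CPM, and a pectinesterase (Bhs1115_028V1.1, scaffold 1115, 342778 to 345736) 92.1 ± 16.6 CPM, a count ratio of 942 (interval 260 to 7780). TGA transcription factors were among the largest decreases named by the rule. Bhs6708_008V1.1 fell from 86.5 ± 14.6 CPM to no counts, at least 614-fold lower, and Bhs539_036V1.1 (scaffold 539, 520779 to 521423) from 120 ± 10.7 to 0.0872 ± 0.151 CPM, a count ratio of 1280 (interval 354 to 10600). A cytochrome P450 (Bhs11692_002V1.1, scaffold 11692, 9994 to 12276) fell from 24.7 ± 1.59 CPM to no counts, at least 175-fold lower. The early light-induced genes Bhs2978_003V1.1 and Bhs474_011V1.1 (scaffold 474, 478830 to 479586) had log2 changes of -9.87 ± 0.17 (SE) and -9.79 ± 0.20. Adjusted p-values of these 10 genes were 4.69e-12 or less, apart from 5.12e-11 for the EREBP-like factor.

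Cell wall genes had 79 of 110 members higher and 23 lower, with a median log2 change of 3.30 (adjusted p of camera 2.82e-07, adjusted p = 0.116 with an estimated correlation). A cellulose synthase (Bhs103_027V1.1) was at 563 ± 19.9 against 42.1 ± 0.387 CPM. Of 34 light-harvesting and photosystem genes 28 were higher and 5 lower, with a median of 3.07, and the photosystem II 22 kDa component (Bhs51_010V1.1) was 126-fold higher (adjusted p of camera 2.92e-10, adjusted p = 0.116 with an estimated correlation). Calvin cycle enzymes had 15 of 21 higher and 6 lower, with phosphoribulokinase (Bhs6932_002V1.1) 49-fold higher (adjusted p of camera 4.41e-06, adjusted p = 0.0659 with an estimated correlation), and chlorophyll biosynthesis 13 of 14 higher and 1 lower (adjusted p of camera 8.41e-06, adjusted p = 0.0659 with an estimated correlation). Plastid and mitochondrial ribosomal proteins had 22 of 31 higher and 4 lower (adjusted p of camera 0.00805, adjusted p = 0.116 with an estimated correlation), and the core organelle list 16 of 18 higher and 2 lower (0.00805, and adjusted p = 0.116 with an estimated correlation). Aquaporins had 9 of 11 higher and 1 lower, with a median of 5.31, or 5.23 with absent genes at their bound (adjusted p of camera 0.00499, adjusted p = 0.412 with an estimated correlation). In the auxin list 61 of 84 genes were higher and 16 lower, with auxin response factor 6-like (Bhs19_008V1.1) at 191 ± 10 against 9.64 ± 1.82 CPM (adjusted p of camera 0.00606, adjusted p = 0.116 with an estimated correlation).

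All 13 early light-induced genes were lower, with a median of -7.83, or -6.51 with absent genes at their bound (adjusted p of camera 1.34e-13, adjusted p = 0.116 with an estimated correlation). Of LEA and dehydrin genes, 20 of 26 were lower and 3 higher, with a median of -2.86 (adjusted p of camera 2.35e-09, adjusted p = 0.116 with an estimated correlation). Translation factors had 59 of 83 lower and 15 higher (adjusted p of camera 0.000856, adjusted p = 0.116 with an estimated correlation), splicing factors 59 of 92 lower and 20 higher (0.00437, and adjusted p = 0.116 with an estimated correlation), and ribosome biogenesis 49 of 83 lower and 20 higher (0.0358, and adjusted p = 0.46 with an estimated correlation). A translation initiation factor 4B (Bhs316_014V1.1) was at 52.1 ± 3.66 against 390 ± 23.2 CPM and splicing factor 3B subunit 2 (Bhs45_047V1.1) at 68.9 ± 2 against 292 ± 14.6 CPM. Proteasome genes had 36 of 57 lower and 9 higher (adjusted p of camera 0.0296, adjusted p = 0.116 with an estimated correlation), with regulatory subunit T5 (Bhs2_103V1.1) 4.4-fold lower. The glyoxylate cycle, beta-oxidation and alternative oxidase list had 6 of 9 lower and 3 higher (adjusted p of camera 0.0192, adjusted p = 0.116 with an estimated correlation), with acyl-coenzyme A oxidase 2 (Bhs5995_006V1.1), an enzyme of fatty acid breakdown, at 49.2 ± 2.34 against 409 ± 26.9 CPM. The ribosome biogenesis call ended without desiccated replicate 1 (adjusted p 0.0561) and, a setting chosen after seeing the data, without the 3 libraries numbered 1 (0.0576), with 0.00173 to 0.0576 over 17 settings.

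The phenylpropanoid list did not pass in this comparison, with 38 of 64 genes higher and 16 lower (17 adjusted over the list alone, adjusted p of camera 0.0583), but passed without 100% rehydrated replicate 3 (0.0489), with 0.0284 to 0.104 over 17 settings. A caffeoyl-CoA O-methyltransferase (Bhs378_031V1.1) was 60.9-fold higher and another (Bhs6_132V1.1) 11.2-fold lower. Heat stress transcription factors had 11 of 18 genes lower and 5 higher (0.0514). They passed without desiccated replicate 2 (0.0372) or 3 (0.0447), without 50% rehydrated replicate 2 (0.0443) or 3 (0.0459), without 100% rehydrated replicate 3 (0.0478), under total count scaling (0.0476), without the 50 genes with the highest counts (0.0485) and, a setting chosen after seeing the data, with the length trend removed (0.0417), with 0.0176 to 0.0912 over 17 settings. Small heat shock proteins had 3 of 10 higher and 6 lower (0.691), with a median of -0.93 and a test pointing down but a mean of 0.27, and the other chaperones 34 of 106 higher and 52 lower (0.144). A heat shock 70kDa protein gene (Bhs12480_001V1.1) was at 128 ± 4.2 against 1590 ± 25.1 CPM. NAC, WRKY and AP2/ERF factors had 63 of 133 higher and 46 lower (0.335), lipoxygenases and phospholipases 25 of 51 higher and 21 lower (0.556), and the ABA list 24 of 62 higher and 34 lower (0.192). Antioxidant enzymes had 32 of 65 higher and 18 lower (0.365), raffinose, sucrose and trehalose metabolism 11 of 29 higher (12 adjusted over the list alone) and 15 lower (0.261), and autophagy 2 of 12 higher and 7 lower (6 adjusted over the list alone, 0.242). Cytosolic ribosomal proteins had 38 of 88 higher and 24 lower (0.866), histones 24 of 37 higher and 8 lower (0.186), cell cycle genes 59 of 108 higher and 34 lower (35 adjusted over the list alone, 0.407), and chlorophyll breakdown and senescence 4 of 9 higher and 5 lower (0.691). Against these counts, summed CPM was lower for cell cycle (3520 ± 111 against 6080 ± 215), antioxidant (9210 ± 267 against 10300 ± 256), lipoxygenase and phospholipase (4200 ± 89.6 against 5020 ± 141) and NAC, WRKY and AP2/ERF genes (3860 ± 169 against 4770 ± 76.3 CPM). It was higher for raffinose metabolism (14100 ± 795 against 11900 ± 344 CPM). Seed storage markers had 2 of 8 higher and 5 lower (0.215), flower and pollen markers 2 of 4 higher and 0 lower, and oil body genes 1 of 3 higher and 1 lower. Without a filter on low counts, histones (adjusted p 0.017, with 0.017 to 0.327 over 17 settings), heat stress transcription factors (0.0176) and the phenylpropanoid list (0.0284) passed.

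Both steps together show where a change went on or turned back. Of the 14776 genes, 8563 were called in both steps by edgeR's quasi-likelihood test, 3130 in the first alone, 1984 in the second alone and 1099 in neither. The steps share the 50% rehydrated libraries, and 20 simulations with unchanged groups gave 0 genes called in both. Since no gene changed in these simulations, they do not show how the shared libraries affect the classes of changed genes. Genes that rose in both steps numbered 2720, against 2299 for independent lists of calls, and genes that fell in both steps 2154, against 1884. Genes that rose and then fell numbered 2102, against 2096, and genes that fell and then rose 1587, against 2067. Total count scaling gave 2526 genes that rose and then fell and 1122 that fell and then rose, and limma on log2(RPKM + 1) 2524 and 1146, so the sizes of these classes depend on the scaling. The log2 changes of both steps correlated at r = 0.036 across genes, which are not independent replicates, against a simulated -0.481, with a covariance of 0.0983 against -0.0156, a difference of 0.1139. Of the light-harvesting and photosystem genes, 24 of 34 rose in both steps, as did 12 of 21 Calvin cycle genes and 40 of 110 cell wall genes. Of the phenylpropanoid genes, 30 of 64 rose and then fell, as did 53 of 133 NAC, WRKY and AP2/ERF genes and 27 of 88 cytosolic ribosomal protein genes. Of the LEA and dehydrin genes, 15 of 26 fell in both steps and 7 rose and then fell, and of the early light-induced genes 7 of 13 rose and then fell. Camera called 12 lists in the first step, 8 up and 4 down, 16 in the second, 7 up and 9 down, and 15 over both, 8 up and 7 down. With an estimated correlation, 1 of these calls held in the first step (phenylpropanoid and flavonoid enzymes), 9 in the second and 0 over both. The 9 were LEA, early light-induced, Calvin cycle, chlorophyll biosynthesis, proteasome, raffinose, phenylpropanoid, ABA and core organelle genes. They share the same adjusted p of camera, just under the threshold, so they passed together rather than each by a margin of its own.

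**Figure D3:**
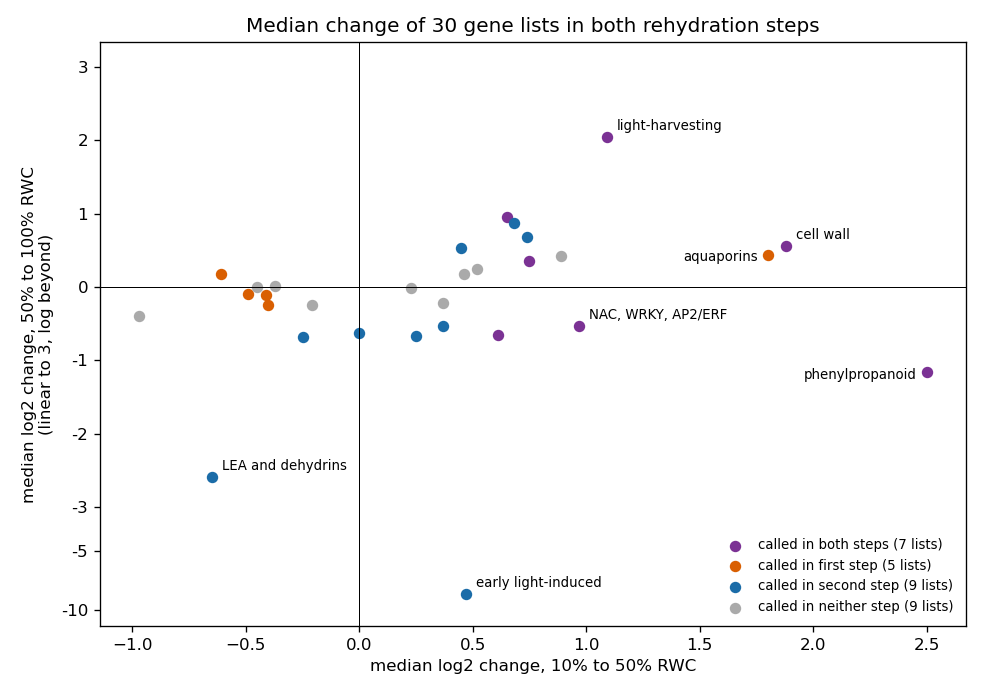
Median log2 change of 30 gene lists from 10% to 50% RWC (horizontal axis) and from 50% to 100% RWC (vertical axis, linear to 3 and logarithmic beyond), each point a list, coloured by the steps in which camera called it. Light-harvesting genes lie at 1.09 and 2.05, phenylpropanoid genes at 2.50 and -1.16 and early light-induced genes at 0.47 and -8.23, and 7 lists were called in both steps.

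The authors' deposited table gives 10859 calls among 23488 genes for the step from 10% to 50% RWC, 5710 higher and 5149 lower. In the authors' deposited table, 14766 of the genes tested here are listed, with 10428 calls, of which 10426 were also called here in the same direction and 0 in the other. The remaining 2 were called only in the authors' deposited table, and 1267 only here. Log2 changes here and in the authors' deposited table correlated at r = 0.946 across genes.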

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

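The splits of the libraries and the test of the 50% rehydrated libraries shared by both steps were set before their results were seen, and all other tests in this part were chosen after. Differences between the leaf states themselves stay open for each pattern, as an untested biological explanation.

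Other splits of the libraries were fitted in the same way. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. The real splits called 11285 genes from 10% to 50% RWC, 10332 from 50% to 100% RWC and 12153 over both, against 0, 0 and 0 in the highest other split, so that 1, 1 and 1 of the splits were as large, the real one counted. For lists called by camera, the real splits gave 12, 17 and 16 and the highest other splits 16, 15 and 16, with 5, 1 and 2 of the 10 splits as large, again with the real one counted. Every other split of 6 libraries mixes both states in unequal parts on each side. It thus keeps part of the real difference and adds the rest to the spread within a side. Neither its genes nor its lists are therefore counts for unchanged groups. For a difference among any of the 3 groups, 100 splits of the 9 libraries were drawn. Only the real split, 1 of 100, called as many as 13687 genes (highest other 7662), which argues against a chance division of the libraries. Other splits can keep libraries of a group together, so 7662 is not a count for unchanged groups.

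Early light-induced and LEA transcripts fell between 50% and 100% RWC. The choice of TMM scaling is argued against as the cause, since the median log2 change over both lists was -3.9 under total count scaling. Both scalings are relative to the library, and a change in the amount of messenger RNA per leaf was not measured. Reads moving between near-identical copies would raise some copies as others fell. In this step 13 of 13 early light-induced genes and 25 of 26 LEA genes were lower, with 0 higher in either list. The sums therefore had to fall and are no separate test. Their log2 changes, -8.3 for early light-induced genes and -2.2 for LEA genes, give only the size of the fall. Reads left out because they fit several copies are not covered by these sums. Summed early light-induced expression lay between 5039 and 5836 CPM in the 50% rehydrated libraries and between 14.36 and 21.31 CPM in the 100% rehydrated ones. A change in the state of the leaves may account for the fall, as a hypothesis found and tested on the same data.

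Phenylpropanoid and flavonoid transcripts rose to 50% RWC and fell to 100% RWC. Chance values of the 50% rehydrated libraries, which enter both steps with opposite sign, would give such a turn. With the steps taken from different 50% rehydrated libraries, the genes of the list that rose at least 2-fold had median second-step log2 changes of -1.39, -1.32 and -1.17 in the 3 ways to part them, which argues against that cause. Under total count scaling the list's medians were 2.66 in the first step and -1.25 in the second, which argues against the choice of TMM scaling as the cause. Both scalings are relative to the library, and a change in the amount of messenger RNA per leaf was not measured. A passing response of the leaves at 50% RWC may account for the turn, as a hypothesis.

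Splicing factors, translation factors and ribosome biogenesis genes fell between 10% and 50% RWC, with a median log2 change of -0.44 over the members of the 3 lists. With the trend against coding length removed the median was again -0.44, which argues against that trend as the cause. More broken RNA in the rehydrated leaves was taken to lower the covered share of long genes. That share was instead 2.72 percentage points higher in the 50% rehydrated libraries, with no overlap between the groups. The mean coding length weighted by reads was lower there, at 1587 to 1630 against 1673 to 1710 bases. The long genes compared were chosen by their reads in each library, so the covered share does not settle whether broken RNA played a part. Scaling stays open as a cause of part of the change, since the median was -0.27 under total count scaling, where camera still called the 3 lists at the preset correlation, calls that under TMM scaling are lost with an estimated one (adjusted p 0.132, 0.18 and 0.419 with an estimated correlation). It cannot be told apart from a fall of these genes in absolute terms, because no value here gives the amount of messenger RNA per leaf.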

How the results depend on the processing

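The fit without the 3 libraries numbered 1, the removal of the length trend, and the settings applied to the step classes and to the overlap with the authors' deposited table were chosen after the results were seen. Leaving out each of the 9 libraries in turn gave 11283 to 11853 genes called from 10% to 50% RWC, 10059 to 10804 from 50% to 100% RWC, 12213 to 12679 over both and 13659 to 13830 in any of the groups. The lists called numbered 12 to 12, 16 to 17 and 14 to 17. Genes that rose in both steps numbered 2477 to 2644, rose and fell 1944 to 2123, fell and rose 1384 to 1537, and fell in both 1975 to 2171, and 10450 to 10526 calls were shared with the authors' deposited table. The other settings apart from the fold threshold gave 10360 to 12449, 9231 to 11205, 10861 to 13688 and 11886 to 15165 genes. Without the 3 libraries numbered 1, the counts were 11556, 10478 and 12348, of which 11144, 9957 and 12000 were also called with all libraries, each in the same direction. A fold of at least 2, which is stricter by construction, left 6171, 4840 and 8035 genes, 1153, 862, 258 and 414 genes in the step classes in the order above, and 5972 shared calls. Without a filter on low counts 19 lists were called from 10% to 50% RWC, and the cause was not tested. With an estimated correlation, 1, 9 and 0 lists were called, and with fry, which asks another question than camera, 29, 27 and 30. Calls were also lost where the estimated correlation lay below the preset 0.01, as for chlorophyll biosynthesis from 10% to 50% RWC (-0.042). The size of the correlation alone therefore does not account for the losses. The direction of the test turned for lists that camera called in none of these settings, while medians other than that of the proteasome kept their sign, and the cause was not tested. These were the proteasome from 10% to 50% RWC (median 0.16 under total count scaling and 0 with fry, whose adjusted p was 0.041), and antioxidant enzymes from 50% to 100% RWC (0.04 without a filter, 0.21 without the libraries numbered 1, 0.14 to 0.21 leaving out a library, where it turned without desiccated replicate 1, 50% rehydrated replicate 3 and 100% rehydrated replicate 1). Others were ribosome biogenesis (-0.1 without the libraries numbered 1, -0.16 to -0.07 leaving out a library) and splicing factors (-0.12 to -0.09) from 50% to 100% RWC, which turned without 50% rehydrated replicate 1, and cytosolic ribosomal proteins over both steps (0.09 with the length trend removed, 0.09 to 0.17 leaving out a library), which turned without 100% rehydrated replicate 2. Of the values of named genes over the settings, 5869 kept direction and call, 12 no longer passed, all of them through the fold threshold, and 0 turned. The depth limits what can be seen of genes near a count of 3, which equals 0.4 to 0.441 CPM. The alternative of another pseudocount for values without counts was not run, since counts were used.

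With the replicate number as a block, 12067, 11046 and 12682 genes and 14, 17 and 14 lists were called, 13910 genes differed in any of the groups, and 10428 calls were shared with the authors' deposited table. The step classes held 2905, 2253, 1732 and 2320 genes. Under the block the antioxidant list had a median of 0.18 from 50% to 100% RWC, with the test turned upward, and the glyoxylate list over both steps no longer passed (adjusted p 0.0692, with 0.0148 to 0.0692 over 17 settings). Lists that passed with the block but not in the same fit without it were LEA (0.0478, with 0.0354 to 0.55) and cytosolic ribosomal proteins (0.0103, with 0.000622 to 0.276) from 10% to 50% RWC and aquaporins (0.0231, with 0.0231 to 0.0774) from 50% to 100% RWC. Libraries with the same number had deviations from their group means that correlated at r of -0.02 to 0.23, and 6 of the 9 libraries correlated best with their own number, a hint of pairing from the data. The pairs numbered 3 correlated at 0.04, 0.01 and -0.02, and no label says what a number marks, so the numbers were not taken to pair the samples.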

Other observations

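The enrichment of gene ontology processes was chosen after the results were seen, as were the values by coding length. Among the 6746 tested genes with a process term, 562 rose at least 2-fold in both steps and 359 rose and then fell at least 2-fold. Genes that rose in both steps were enriched, by the one-sided Fisher's exact test, in enzyme linked receptor signalling (15 of 48 genes, 4 expected, adjusted p 0.00106), which relays signals across the cell membrane, and in the photosynthetic electron transport chain (11 of 27, 2.2 expected, 0.00106). Generation of precursor metabolites and energy (13 of 47, 3.9 expected, 0.00928), response to radiation (15 of 66, 5.5 expected, 0.0227) and fatty acid biosynthesis (11 of 42, 3.5 expected, 0.0367) followed. Genes that rose and then fell were enriched in phenylpropanoid biosynthesis (9 of 31, 1.6 expected, 0.0038), response to other organisms (17 of 111, 5.9 expected, 0.00928), response to abiotic stimuli (14 of 83, 4.4 expected, 0.0103) and the broad term metabolic process (51 of 469, 25 expected, 0.000345). Of 173 terms, 0 passed among the 73 genes that fell and then rose and 0 among the 158 that fell in both steps.

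Transcripts of oil body proteins, which coat stored lipid, summed to 566 ± 12 CPM (SD, n = 3) in desiccated, 361 ± 9.24 CPM in 50% and 61.3 ± 2.41 CPM in 100% rehydrated leaves. A single caleosin (Bhs39_021V1.1), at 562, 357 and 50.3 CPM, made up most of the sum, while another (Bhs39_022V1.1) stood at 1.96, 3 and 10.1 CPM. Seed storage markers summed to 1310 ± 205, 543 ± 49.6 and 456 ± 75.1 CPM, and flower and pollen markers to 110 ± 7.98, 219 ± 7.46 and 444 ± 24.8 CPM, in the same order. From 50% to 100% RWC the flower and pollen sum rested on a LAT61 gene (Bhs7_121V1.1), from 64.9 to 243 CPM, while 2 of 4 members fell and the list's median log2 change was -0.49. The summed core organelle genes stood at 974 ± 66.7, 1470 ± 166 and 5950 ± 513 CPM, with list medians of 0.68 in the first step and 0.88 in the second. A psbP gene (Bhs1317_004V1.1), encoded in the nucleus of plants, went from 253 over 476 to 2960 CPM and carried much of the last rise, so this sum does not measure organelle RNA alone. With the genes in 5 equal groups by coding length, the group of the longest genes had a median log2 change of -0.07 from 10% to 50% RWC, 0.01 from 50% to 100% RWC and -0.15 over both, and Spearman's rho of the change with length across genes, which are not independent replicates, was -0.031, -0.031 and -0.047. With the steps taken from different 50% rehydrated libraries, the correlation of both steps across genes was 0.018 to 0.025.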
